A study of Mus musculus and Homo sapiens with 25 samples.

How the data were processed

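The series holds 25 samples in 25 groups, so each group has 1 library and there are no replicates. RNA-seq was run on 10 libraries of mouse splenic B cells. Chromatin immunoprecipitation with sequencing (ChIP-seq) was run on 12 mouse libraries and 3 human ones. Mouse B and T cells were isolated with kits for resting or naive cells, per the labels. Per the labels, B cells were stimulated with an anti-IgM F(ab')2 fragment, an antibody to CD40 and the interleukins IL-2, IL-4 and IL-5, and CD4 T cells with anti-CD3 and anti-CD28. The inhibitor was 11R-VIVIT, a cell-permeable peptide that blocks the docking of NFAT on calcineurin, given at 5 µM in dimethyl sulfoxide (DMSO) from the start of culture. The HA libraries came from B cells activated for 24 h, transduced with a retrovirus carrying an HA-tagged factor and GFP, and fixed 48 h later, per the labels.

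The authors deposited, for RNA, read counts per RefSeq transcript or transcript group and RPKM, per the file headers. The counting tool, the strand setting, the handling of read pairs and of isoforms, the filters and the library total used for RPKM are not given in the sources used here. For ChIP, each deposited table holds 1 line per summit with the signal (read pileup at the summit), the fold over local background (a ratio), and −log10 p and −log10 q values, per the file headers. No normalization of the pileup is stated, and the control, the removal of duplicates, the thresholds and any pooling are not given in the sources used here. The background that pileup and fold imply was not local, but nearly 1 value per library. Over most summits it ran from 0.536665 to 0.536667 in HA-IRF4 and from 2.25891 to 2.25892 in B cell H3K27ac at 0 h. The folds and the ranks built on them therefore show no correction for local bias. The authors' tables also assign each summit to a RefSeq gene and a class such as promoter or intron, by a rule that is not given in the sources used here. The genome builds were mm10 and hg19. STAR 2.4.2a, Bowtie 1.1.1 and MACS2 2.1.0.20140616 are named in the submitters' processing notes, without their settings. A peak's fold and scores are the authors' own and were used only to rank, filter or describe peaks.

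The 26099 RNA lines were summed to 23343 gene symbols (138 lines carried joined symbols). Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and peaks in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The 11229 genes with a mean of at least 1 CPM (counts scaled to library size) were tested with the edgeR quasi-likelihood test after TMM scaling. The model had time and treatment as additive terms over all 10 libraries, which left 4 residual degrees of freedom. The lone 0 h library was thereby assumed to vary like the others. P-values were adjusted with the Benjamini-Hochberg method at 0.05. They measure only the spread between these libraries, which may be technical. CPM values in the text are TMM-scaled. A treatment effect that differs between 4, 24 and 48 h enters the residual of this model.

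Gene lists were written, and tests, filters, the naming rule and most alternatives chosen, before the data were examined. Of 27 lists, 25 were tested on RNA with camera (preset correlation 0.01, also with an estimated correlation) for 5 contrasts, adjusted over all of these. The other 2 hold T cell genes and were used for H3K27ac. List calls were also adjusted over the list alone, and where the text gives no second count this one was the same. Of 10 list symbols missing in the tables, 6 were matched by a synonym and 4 were not matched. At single times, where each arm is 1 library, log2 ratios of CPM with a prior count of 2 are given without p-values. List medians there were set beside 10000 random lists matched on mean expression in 50 bins. Induced and lost genes were those at least 4-fold higher or lower in the untreated library of a time than at 0 h, with a mean CPM of at least 5. Where all libraries of a group had 0 counts, a fold was computed against 3 counts per library and is a lower bound. With 1 to 3 counts at 0 h, a ratio carries its 95% counting interval. Intervals and floors cover counting error only.

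Genes named in the text follow a rule. It took the 8 called genes with the highest and the 8 with the lowest log2 fold change per activation time and for the inhibitor, with a mean CPM of at least 10 and the same sign in every library of that time (for the inhibitor, at all 3 times). Symbols of predicted genes and small RNAs were left out. It added the 2 members of each list with the largest called change, 17 genes fixed in advance, and at single times the 5 highest and 5 lowest ratios with a mean CPM of at least 10. Marker levels and other genes named outside this rule were chosen after their values were seen, and are said to be so. Some genes that the rule names are not reported here.

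Summits of 1 region were merged, and regions counted as overlapping when they shared at least 1 bp. Because the number of called regions differed widely between libraries, equal numbers of the strongest regions by fold were compared: 3839 for B cells over all times, 8132 for T cells, and 5000 for the HA and for the human libraries. Shares carry Wilson 95% intervals, and list shares exact binomial ones. The regions of 1 library were also placed at random 100 times on the same chromosomes. Genes assigned to the 2000 strongest regions shared by the 3 HA libraries, and to regions of 1 library alone, were tested with camera in the RNA fit. Chosen after the data were seen were a search for regions under 700 bp with a fold of at least 15 over exons, the distance from the 10000 strongest summits of one library to the nearest of 30000 in another, rank correlations of fold over bins of 1000 bp, a comparison that pools DMSO and untreated libraries, and leaving out single libraries.

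The steps were tested on simulated data. In simulated counts for activation at 4 h, 20.6% of the 107 genes changed 2-fold and 81.7% of the 93 changed 4-fold were recovered, with 2 false calls among 11029 unchanged genes. For the inhibitor against DMSO the shares were 46.5% of 86 and 95.6% of 114, with 6 false calls. These shares hold for simulated counts with a set fold per changed gene. They may not hold for the real inhibitor comparison, where list medians differed between times and the calls hung on single libraries. Alternatives covered other size factors, filters, thresholds, tools and sets of libraries, other ranks, overlaps and peak thresholds. Motifs in the peaks were not analysed here, since that needs a genome sequence.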

Results

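RNA was measured in 10 libraries of mouse splenic B cells: 1 at rest (0 h), and at 4, 24 and 48 h of stimulation 1 each without addition, with DMSO and with 11R-VIVIT. Total counts ran from 44356086 (inhibitor, 24 h) to 63623887 (untreated, 48 h). Acetylation of histone H3 at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was mapped in B cells at 0, 4, 24, 48 and 72 h and in CD4 T cells at 0, 4, 24 and 48 h. Libraries labelled HA-IRF4, HA-IRF8 and HA-NFATc2 were made from B cells at 72 h, 2 of them with labels in doubt (below), and IRF4 (48 h), NFATc1 (24 h) and NFATc2 (24 h) were mapped in human blood CD4 T cells. The H3K27ac lists held 3839 to 63285 regions, the HA lists 63133 to 88181 and the human lists 7054 to 56888. Read depth of the ChIP libraries is not given in these tables. The background that pileup and fold imply is a rough guide to relative depth. For B cell H3K27ac it was 2.25891, 1.10344, 2.7433, 2.34875 and 0.908193 at 0, 4, 24, 48 and 72 h.

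The first comparison asks which genes change when resting B cells are activated through the B cell receptor, CD40 and cytokines. At 4 h the resting B cell program gave way to growth: immediate early factors, MYC targets and ribosome biogenesis rose, while B cell identity and trafficking genes fell. Transcripts of macrophages also fell. Of 11229 genes tested, 2969 rose and 3139 fell with edgeR at 4 h. MYC, which drives growth and ribosome production, rose from 84.1 to 3192 CPM in the untreated library (log2 fold change 5.22 ± 0.28 SE, edgeR adjusted p 8.03e-05). EGR2, a zinc finger factor induced by antigen receptors, had 12.7 CPM at 0 h and 948 at 4 h (6.21 ± 0.28, edgeR adjusted p 7.63e-05). Other immediate early factors with large increases were Fosl1 (9.93 ± 1.52), Nr4a2 (7.82 ± 1.16), Nr4a3 (7.64 ± 0.29) and Maff (6.78 ± 0.38). Of 23 immediate early transcription factors 14 rose and 1 fell (15 and 1 adjusted over the list alone), with a median log2 change of 2.4 (camera adjusted p 1.96e-09, adjusted p = 0.166 with an estimated correlation). All 37 genes of ribosome biogenesis and MYC targets rose, with a median of 2.70 (camera adjusted p 1.66e-23, adjusted p = 0.192 with an estimated correlation). Among them were Odc1 (4.16 ± 0.26), the first enzyme of polyamine synthesis, and Srm (3.83 ± 0.45), the next one. Of 44 cytoplasmic ribosomal proteins 37 rose and none fell (39 adjusted over the list alone), by a median of 0.61, with Rps2 at 1.00 and Rpl8 at 1.08 ± 0.17 (camera adjusted p 4.94e-04, adjusted p = 0.599 with an estimated correlation).

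Genes that answer signalling pathways followed at the same time. Of 21 NFAT target genes with enough counts 13 rose and none fell, also adjusted over the list alone, with a median of 2.65 (camera adjusted p 8.32e-08, adjusted p = 0.166 with an estimated correlation). Interleukin 10 mRNA (Il10) went from 0.0792 to 25.5 CPM, a log2 change of 8.79 ± 1.49 (edgeR adjusted p 0.00248), and did not pass at 24 h or 48 h. The chemokine genes Ccl4 (8.70 ± 1.1) and Ccl3 (7.71 ± 1.33) rose as well. Of 25 NF-kB target genes 15 rose and 3 fell (median 1.29, camera adjusted p 2.25e-05, adjusted p = 0.333 with an estimated correlation). They included Bcl2l1 (5.31 ± 0.33), which keeps activated B cells alive, and Tnfaip3 (4.59 ± 0.40), an inhibitor of NF-kB signalling. Of 26 IL-4 and STAT6 response genes 19 rose and 1 fell (median 1.90, camera adjusted p 2.98e-09, adjusted p = 0.126 with an estimated correlation), led by Nfil3 (6.28 ± 0.30). Cytokines and chemokines went both ways, with 7 of 22 up and 4 down (7 and 6 adjusted over the list alone, camera adjusted p 0.205). Among 28 genes of the NFAT family and calcineurin pathway 2 rose and 13 fell (camera adjusted p 0.0785). Orai1, the pore of the store-operated calcium channel, rose by 3.31 ± 0.28, and Itpr3, a calcium release channel, changed by -2.85 ± 0.45.

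B cell surface and signalling genes went down at 4 h. Of 28 B cell identity genes 20 fell and 4 rose (20 and 6 adjusted over the list alone), with a median of -1.94 (camera adjusted p 4.90e-06, adjusted p = 0.333 with an estimated correlation). Syk, the kinase next to the B cell receptor, changed by -3.69 ± 0.24, Fcgr2b, the inhibitory Fc receptor, by -3.96, and Fcrla by -5.42 ± 0.30. Of 26 quiescence and trafficking genes 15 fell and 4 rose (median -1.44, camera adjusted p 0.0195, adjusted p = 0.683 with an estimated correlation). Here S1pr4, a receptor for sphingosine phosphate, changed by -4.81 ± 0.24, while Il7r changed by 4.71 ± 0.71. Among 29 interferon response genes 15 fell and none rose (median -1.44, camera adjusted p 0.0135, adjusted p = 0.721 with an estimated correlation). Of the single genes, Slc40a1, which encodes the iron exporter ferroportin of macrophages, had a log2 change of -6.43 ± 0.35, March1 of -6.26 ± 0.83, Ceacam1 of -6.08 ± 0.77 and Hhex of -5.49 ± 0.35. Of 20 monocyte and macrophage markers 18 fell (19 adjusted over the list alone), by a median of -3.97 (camera adjusted p 6.39e-10, adjusted p = 0.166 with an estimated correlation). Among the other cell types, 6 of 20 NK and dendritic cell markers fell and 2 rose, 3 of 20 T cell markers fell and 1 rose (2 and 1 adjusted over the list alone), 2 of 4 neutrophil markers fell, and 1 of 12 erythroid markers rose, the transferrin receptor Tfrc (2.91 ± 0.49). These 4 lists had no camera call at 4 h (adjusted p 0.508 to 0.808).

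By 24 h cholesterol genes were up, and the cell cycle list, which had 9 members up and 8 down at 4 h (9 and 7 adjusted over the list alone), rose almost as a whole. With edgeR 2870 genes rose and 2186 fell. The count moved to 2649 without the untreated 24 h library. Of 40 cell cycle genes 32 rose and 1 fell (35 and 1 adjusted over the list alone), with a median of 2.13 (camera adjusted p 9.06e-10, adjusted p = 0.443 with an estimated correlation). The replication licensing genes Cdc6 (3.01) and Mcm6 (2.96 ± 0.21) were among them. At 4 h the median of this list was -0.23, while its camera direction was up (adjusted p 0.751). Cholesterol biosynthesis had 17 of 23 genes up and 4 down at 4 h and all 23 up at 24 h, with a median of 2.32 (camera adjusted p 2.07e-15, adjusted p = 0.153 with an estimated correlation). Idi1, an enzyme gene of isoprenoid synthesis, changed by 3.77. Of 30 unfolded protein response genes 18 rose and 1 fell (20 and 1 adjusted over the list alone, camera adjusted p 3.66e-05, adjusted p = 0.222 with an estimated correlation). Glycolysis had 13 of 24 genes up and 1 down (camera adjusted p 1.36e-06, adjusted p = 0.166 with an estimated correlation). The genes highest over 0 h included Pdcd1, an inhibitory receptor (8.71 ± 0.85), the chemokine gene Ccl22 (7.48 ± 0.25), the cytokine signalling inhibitor Cish (7.40 ± 0.42), Rgs16 (7.36 ± 1.47) and Bcat1 (7.25 ± 0.64). Cyp1a1, a target of the aryl hydrocarbon receptor, had no counts at 0 h and was at least 637-fold higher.

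Loss of the resting program went on at 24 h. Of the B cell identity genes 22 of 28 fell and none rose (median -1.67, camera adjusted p 1.85e-12, adjusted p = 0.244 with an estimated correlation). Cr2, the complement receptor CD21, changed by -4.66 ± 0.20. Quiescence and trafficking genes fell in 19 of 26 cases and rose in 1 (camera adjusted p 4.40e-10, adjusted p = 0.295 with an estimated correlation), among them S1pr1 (-5.40), which lets lymphocytes leave lymph nodes. Marginal zone and B1 cell genes had 10 of 20 down and 3 up (13 and 3 adjusted over the list alone, median -1.54, camera adjusted p 0.00522, adjusted p = 0.166 with an estimated correlation). Markers of other cells fell to differing degrees. All 20 macrophage markers fell, by a median of -6.19 (camera adjusted p 1.23e-25, adjusted p = 0.153 with an estimated correlation). C1qa, the complement component made by macrophages, went from 86.5 to 0.25 CPM. Of 12 erythroid markers 10 fell and 1 rose (11 and 1 adjusted over the list alone), all 4 neutrophil markers fell, 10 of 20 T cell markers fell and 1 rose (median -1.70), and 10 of 20 NK and dendritic cell markers fell and 3 rose. Camera called each of these 4 lists down (adjusted p 6.71e-11 for erythroid, 0.00971 for neutrophil, 0.00459 for T cell and 0.00106 for NK and dendritic cell markers), with an adjusted p = 0.166 to 0.333 under an estimated correlation.

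At 48 h the cell cycle, glycolysis, cholesterol and ribosome lists were up. EdgeR called 3378 genes up and 2886 down. Of 40 cell cycle genes 37 rose and 1 fell, with a median of 3.21 (camera adjusted p 3.06e-14, adjusted p = 0.337 with an estimated correlation). Ccnb1, the cyclin of mitosis, changed by 4.83 ± 0.63 and Cdc20 by 4.79 ± 0.48. Glycolysis genes rose in 17 of 24 cases and fell in 1, with a median of 2.77 (camera adjusted p 1.12e-11, adjusted p = 0.153 with an estimated correlation). The lactate exporter gene Slc16a3 changed by 6.49 ± 1.23 and Tpi1 by 4.40 ± 0.17. All 23 cholesterol genes were up again, by a median of 2.69 (camera adjusted p 2.52e-14, adjusted p = 0.166 with an estimated correlation). Ribosome biogenesis genes were up in 36 of 37 cases at both 24 and 48 h (camera adjusted p 1.22e-15 and 9.66e-12, adjusted p = 0.279 and 0.322 with an estimated correlation), and ribosomal proteins in 42 and 41 of 44 (camera adjusted p 2.17e-10 and 5.12e-10, both with adjusted p = 0.333 with an estimated correlation). Adjusted over the list alone these counts were 37 and 36, and 44 and 42. The largest ratios over 0 h included Stc2, a secreted glycoprotein (1251-fold in the untreated library, counting interval 346 to 10348), the chemokine gene Ccl17 (917-fold, 254 to 7584), and Penk (at least 337-fold), Edn1 (at least 388-fold) and Ccl1 (at least 644-fold), the last 3 with no counts at 0 h. Raver1-fdx1l, a readthrough transcript whose counts could belong to its neighbours, is left as uncertain.

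Down at 48 h were 24 of 28 B cell identity genes with none up (median -2.32, camera adjusted p 1.48e-13, adjusted p = 0.251 with an estimated correlation). Cr2 reached -6.48 ± 0.21 and Bank1, an adaptor of B cell receptor signalling, -5.01. Quiescence and trafficking genes fell in 19 of 26 cases and none rose (19 and 1 adjusted over the list alone, camera adjusted p 1.67e-08, adjusted p = 0.322 with an estimated correlation), with S1pr1 at -6.99 ± 0.57. Interferon response genes fell in 11 of 29 cases at 24 h and 18 at 48 h, and rose in 2 and 1 (camera adjusted p 0.0162 and 1.53e-05, adjusted p = 0.721 and 0.464 with an estimated correlation). Oas2, an antiviral sensor of double-stranded RNA, changed by -7.36 at 48 h and Ifit3 by -5.49. Slc40a1 went from 8127 counts at 0 h to 0 in the untreated, 1 in the DMSO and 4 in the inhibitor library. Haemoglobin transcripts fell too, although Hba-a1 and Hba-a2, and Hbb-b1 and Hbb-bs, share reads and their split is uncertain. Macrophage markers were down in 19 of 20 cases (camera adjusted p 3.53e-23, adjusted p = 0.166 with an estimated correlation), all 4 neutrophil markers fell (6.76e-04 and 0.322), 10 of 12 erythroid markers fell and 1 rose (4.72e-13 and 0.166; median -10.17, or -7.54 with 4 members without counts at their bound), and 11 of 20 NK and dendritic cell markers fell and 4 rose, or 11 and 5 adjusted over the list alone (0.00766 and 0.380). T cell markers fell in 8 of 20 cases and rose in 2, with no camera call (adjusted p 0.193).

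Several lists split in their response. NFAT target genes had 8 of 21 up and none down at 24 h (6 adjusted over the list alone) and 7 up and 3 down at 48 h (camera adjusted p 0.00207 and 0.0162, adjusted p = 0.312 and 0.364 with an estimated correlation). IL-4 and STAT6 response genes had 14 of 26 up and 2 down at 24 h and 17 up and 3 down at 48 h (camera adjusted p 4.31e-08 and 3.80e-08, both with adjusted p = 0.126 with an estimated correlation). Marginal zone and B1 genes had 5 of 20 up and 6 down at 4 h and 3 up and 12 down at 48 h (camera adjusted p 0.748 and 5.49e-05, the latter with adjusted p = 0.172 with an estimated correlation). Unfolded protein response genes rose in 15 of 30 cases and fell in 3 at 4 h, and rose in 17 and fell in 3 at 48 h (camera adjusted p 0.00236 and 0.0191, adjusted p = 0.322 and 0.380 with an estimated correlation). No camera call was made at any of the 3 times for germinal centre genes (8, 6 and 7 of 26 up, 11, 9 and 11 down; 9, 6 and 7 up and 11, 10 and 11 down adjusted over the list alone), plasma cell genes (8, 5 and 6 of 28 up, 8, 5 and 6 down, with 4 down at 24 h adjusted over the list alone) or apoptosis regulators (10, 8 and 13 of 26 up, 5, 5 and 6 down, with 7 down at 48 h adjusted over the list alone). The germinal centre marker Gcsam changed by -7.75 at 24 h, the plasma cell factor gene Ell2 by 2.82 ± 0.44 at 4 h, and the survival gene Bcl2a1d by 4.38 ± 0.32 at 4 h. At 4 h glycolysis had 11 of 24 genes up and 7 down (11 and 8 adjusted over the list alone, camera adjusted p 0.0754), and cholesterol synthesis was already called (camera adjusted p 2.32e-04, adjusted p = 0.312 with an estimated correlation). Without a camera call at 24 and 48 h were immediate early factors (8 and 10 of 23 up, 5 and 6 down), NF-kB targets (8 and 9 of 25 up, 4 and 6 down), NFAT pathway genes (4 and 4 of 28 up, 7 and 10 down), and cytokines (5 and 6 of 22 up, 5 and 10 down). For cytokines at 48 h the median was -0.59 while the camera direction was up. No list call at any time held with an estimated correlation.

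The factors that the series is about followed different courses. Irf4 (chromosome 13, 30749258 to 30766927) rose from 250 to 4407 CPM at 4 h in the untreated library (4.26 ± 0.36, edgeR adjusted p 0.000190) and was at 308 CPM at 24 h and 361 at 48 h, neither of which passed. Irf8 (chromosome 8, 120736376 to 120756692) had smaller increases, 1.1 ± 0.35 at 4 h and 0.98 ± 0.34 at 48 h (edgeR adjusted p 0.0319 and 0.0447). Nfatc1 rose by 1.87 ± 0.21 at 4 h and 0.61 at 24 h (edgeR adjusted p 0.000500 and 0.0409). Nfatc2 went the other way, from 54.1 to 10.2 CPM at 4 h (-2.58 ± 0.21, edgeR adjusted p 0.000167), and did not pass at 24 or 48 h. Nfatc3 changed by -1.26 ± 0.26 at 48 h. Among the partners of IRF4 and IRF8, Batf rose at all 3 times (3.81 ± 0.21 at 4 h), while Spi1 (Sfpi1 in the tables, -1.27 ± 0.22 at 4 h) and Spib (-0.93 ± 0.15) fell. IRF factors and partners had 4 of 17 up and 8 down at 4 h, 1 and 8 at 24 h, and 2 and 8 at 48 h (2 and 10 adjusted over the list alone at 48 h). The camera adjusted p-values were 0.660, 0.0478 and 0.0416, the last 2 with adjusted p = 0.462 and 0.485 with an estimated correlation. Of the factors that set B cell fate, Pax5 fell at all 3 times (-1.60 ± 0.34 at 4 h, -2.11 at 48 h), Bcl6 fell (-1.76 ± 0.37 at 4 h), Bach2 changed by -1.75 ± 0.24 at 48 h, and Prdm1 did not pass at any time. Rcan1, a calcineurin inhibitor and NFAT target, rose by 2.57 ± 0.48 at 24 h and 1.60 at 48 h.

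**Figure D1:**
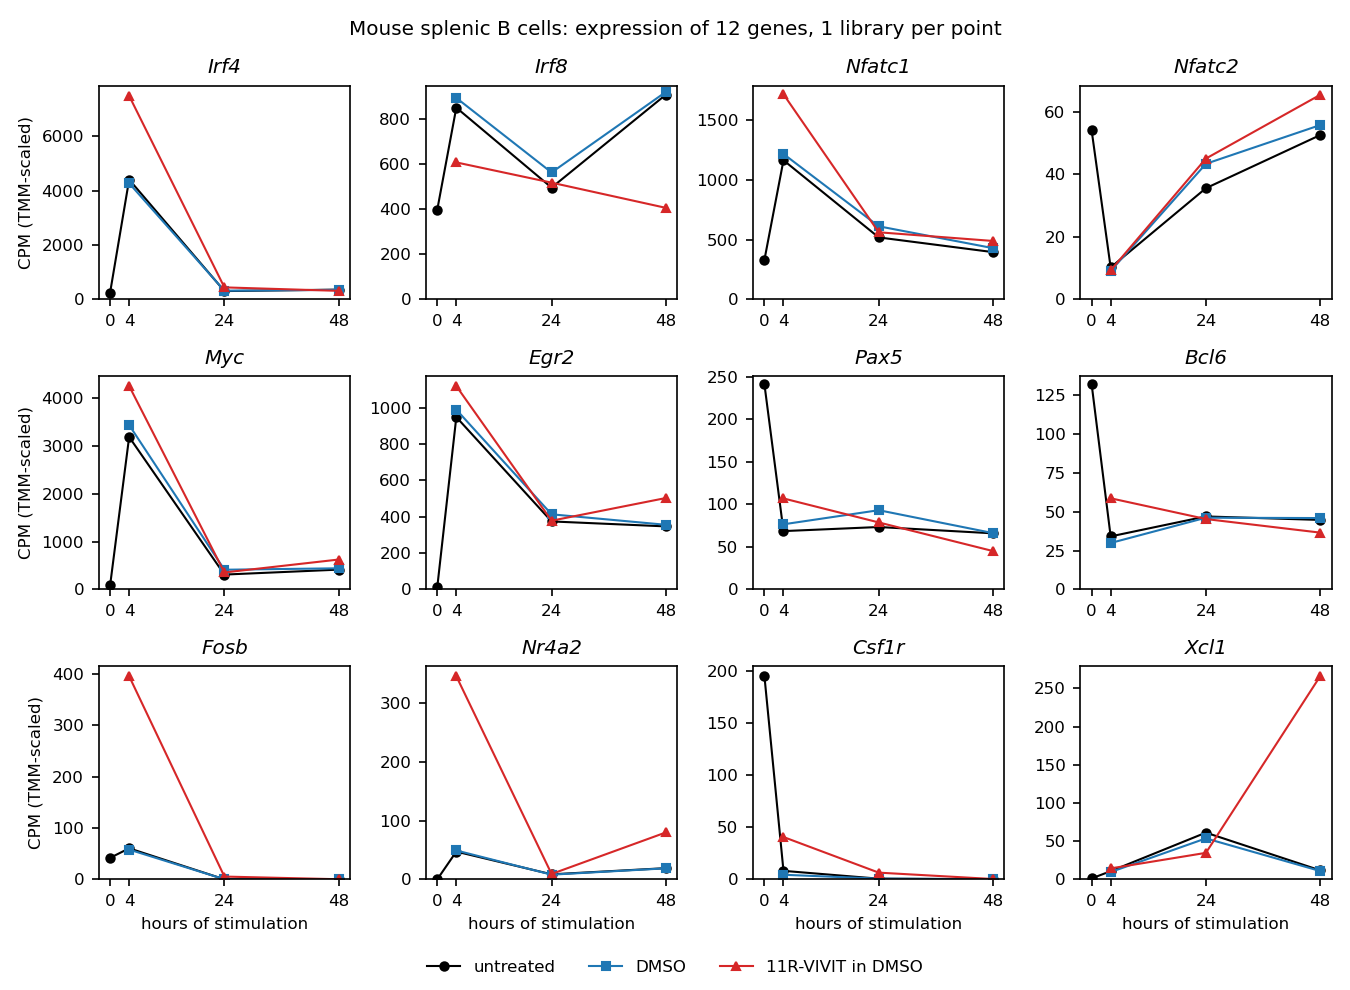
Levels of 12 genes in the 10 B cell RNA libraries, in TMM-scaled CPM against hours of stimulation, for untreated, DMSO and 11R-VIVIT libraries (1 library per point). Irf4, Egr2 and Myc peak at 4 h, and the inhibitor and DMSO points of Fosb, Nr4a2 and Csf1r lie apart at 4 h.

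The next comparison asks which activation genes need NFAT, by setting 11R-VIVIT beside its solvent. Over the 3 times, most of the genes that passed were higher with the inhibitor. With edgeR 56 genes rose and 5 fell, and 1678 had an unadjusted p under 0.05. DESeq2 called 635 and limma on log2 RPKM none. The 61 calls hang on single libraries. They went to 0 without the DMSO library of 4, 24 or 48 h or without the untreated 24 h library, to 4 without the inhibitor library of 24 h, to 5 without the untreated 4 h and 9 without the untreated 48 h library, to 101 without the inhibitor library of 4 h and to 644 without that of 48 h. Without all 4 h libraries 1 gene passed, and without all 24 h libraries none (1182 and 1298 at an unadjusted p under 0.05 for inhibitor against DMSO). The lowest adjusted p belonged to Lrp1, a scavenger receptor gene (2.46 ± 0.18, edgeR adjusted p 0.00921). Others higher were Slc40a1 (2.98 ± 0.29, edgeR adjusted p 0.0235), the protease gene Mmp25 (2.78 ± 0.24), the calcium channel subunit Cacnb3 (2.67 ± 0.26), the mannose receptor gene Mrc1 (2.62 ± 0.37) and the cytokine receptor gene Flt3 (2.56 ± 0.34). The 5 lower genes were Thy1 (-1.3 ± 0.20), on the T cell marker list, Scd2 (-1.1 ± 0.16), Timd2 (-1.08 ± 0.11), Parpbp (-1.00 ± 0.15) and Cbx5 (-0.75 ± 0.11). In the untreated 48 h library Thy1 was at 67.5 CPM and Cd3e, chosen after its values were seen, at 0.33 CPM. Thy1 therefore need not stand for T cells here. Of the 56 higher genes 30 were at least 2-fold lower in the untreated 4 h library than at 0 h, against 27.8% of all genes tested, 12 were at least 2-fold higher, and 7 were on a list of another cell type. None of the factors named above passed. Irf4 had a log2 change of 0.39 ± 0.19 (edgeR adjusted p 0.387) and Irf8 of -0.59 ± 0.22 (edgeR adjusted p 0.282).

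Among gene groups, 4 of 20 macrophage markers rose with the inhibitor and none fell (17 and 0 adjusted over the list alone), with a median of 1.94 (camera adjusted p 1.23e-25, adjusted p = 0.164 with an estimated correlation). Of 12 erythroid markers 1 rose (8 adjusted over the list alone, camera adjusted p 3.93e-10, adjusted p = 0.166 with an estimated correlation), and of 4 neutrophil markers none passed over all genes but 4 rose adjusted over the list alone (camera adjusted p 7.44e-07, adjusted p = 0.166 with an estimated correlation). T cell markers went down, 1 of 20 over all genes and 5 adjusted over the list alone (camera adjusted p 3.66e-05, adjusted p = 0.153 with an estimated correlation). NK and dendritic cell markers had 2 of 20 up (5 up and 4 down adjusted over the list alone, camera adjusted p 0.892). Immediate early factors had 2 of 23 up, Maff (1.36 ± 0.18) and Nr4a3 (0.89 ± 0.13), and 9 adjusted over the list alone, with a median of 0.79 (camera adjusted p 3.06e-14, adjusted p = 0.156 with an estimated correlation). Cytokines and chemokines had 2 of 22 up, Ccl22 (0.84 ± 0.11) and Cxcl16 (2.31 ± 0.30), and 8 adjusted over the list alone (camera adjusted p 1.66e-08, adjusted p = 0.153 with an estimated correlation). NF-kB targets had none (5 up adjusted over the list alone, camera adjusted p 4.51e-05, adjusted p = 0.333 with an estimated correlation). NFAT targets had none (1 up adjusted over the list alone), with a median of 0.49 and camera direction up (adjusted p 0.0162, adjusted p = 0.364 with an estimated correlation). The IL-4 and STAT6 list had 1 of 26 up, or 2 adjusted over the list alone (camera adjusted p 0.0264, adjusted p = 0.227 with an estimated correlation). Camera called cell cycle and interferon genes down and ribosomal proteins up without a single gene passing (adjusted p 0.00938, 0.0415 and 0.00900, adjusted p = 0.765, 0.751 and 0.721 with an estimated correlation). No camera call was made for the other 12 lists. Of these, the B cell identity list had 1 member up (Fcrl1, 1.1 ± 0.13), the unfolded protein response list 1 up (Ppp1r15a, 1.07 ± 0.15), and the others none. Adjusted over the list alone, germinal centre genes had 2 and marginal zone genes 1 down, and IRF factors 1 up. Median and mean differed in sign for the NFAT pathway, IRF, B cell identity, and NK and dendritic cell lists.

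As background, DMSO was set beside no addition in the same fit. No gene passed with edgeR, DESeq2 or limma, and 7 had an unadjusted p under 0.05 with edgeR. The error of this fit also holds inhibitor effects that differ between times. The contrast could therefore call little, and it does not show that DMSO had no effect. The median chi-square per gene between DMSO and untreated libraries was 1.70, 6.09 and 2.44 at 4, 24 and 48 h, where sampling alone gives 0.455. No list member passed. Camera called the immediate early list up (median 0.09, adjusted p 6.73e-04, adjusted p = 0.333 with an estimated correlation) and the macrophage, erythroid and neutrophil lists down (adjusted p 0.00545, 3.64e-05 and 0.0496, adjusted p = 0.437, 0.218 and 0.322 with an estimated correlation). The macrophage median was -0.07 and the erythroid one -0.11. The neutrophil list has 4 members, and its medians for DMSO over untreated were 0.05, 0.12 and -0.95 at 4, 24 and 48 h. At 4 h alone the macrophage median was -0.28 with 4 of 20 markers higher, where random lists spanned -0.0742 to 0.0784.

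The inhibitor was also compared with DMSO at each time, where each arm is 1 library and no replicate check exists. At 4 h many lists were higher with the inhibitor, immediate early and NFAT target genes among them, as were genes that activation had lowered. At 24 h cell cycle genes and the set of induced genes as a whole were lower, though not immediate early, NF-kB and cytokine genes. At 48 h interferon-inducible genes were lower. The standard deviation of log2 ratios over genes was 0.531, 0.413 and 0.652 at 4, 24 and 48 h, against 0.0894, 0.185 and 0.128 between DMSO and untreated libraries. At least 2-fold higher with the inhibitor were 337 of 7284 genes at 4 h, 167 of 8364 at 24 h and 163 of 8281 at 48 h, and at least 2-fold lower were 60, 95 and 689. Between DMSO and untreated libraries 0, 5 and 2 genes differed that much. At 4 h the highest log2 ratios were those of Csf1r, the macrophage growth factor receptor gene (3.16, 40.7 against 4.52 CPM), Fn1 (2.94), Nr4a2 (2.81, 345 against 49.2 CPM), Fosb (2.76, 395 against 58.2 CPM) and Lrp1 (2.76). The lowest included Irgm1 (-1.59) and Ifi47 (-1.48), both interferon-induced GTPases. At 24 h Gpc1 (3.98) and Il12b, a subunit of IL-12 (3.58), led, and Lpl (-2.30) and Il12rb1, a receptor chain for IL-12 (-1.79), were lowest. At 48 h the chemokine gene Xcl1 was highest (4.59, 266 against 11.0 CPM), followed by Cyp1a1 (3.74), Timp1 (3.53), Cyp1b1 (3.10) and Plau (2.87). The lowest were the interferon-induced genes Iigp1 (-6.79, 1.06 against 122 CPM), Gbp6 (-5.0), Tgtp2 (-4.50) and Tgtp1 (-4.46), and Gzmb, a cytotoxic protease gene (-3.95).

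List medians moved with time. Immediate early factors had medians of 1.1, 0.60 and 0.67 at 4, 24 and 48 h, with 22, 19 and 17 of 23 members higher, and cytokines 1.11, 0.45 and 0.62. NF-kB targets had 0.41, 0.34 and 0.01, with 21, 22 and 13 of 25 higher. NFAT targets had 0.61, -0.13 and 0.25, with 16, 8 and 12 of 21 higher, where random lists at 4 h spanned -0.205 to 0.288. Also above their random lists at 4 h were B cell identity (0.47, 21 of 28 higher), germinal centre (0.58), plasma cell (0.39), IL-4 and STAT6 (0.40) and cell cycle genes. T cell markers and unfolded protein response genes (-0.24) lay below theirs at 4 h. Cell cycle genes had 0.22, -0.81 and 0.04, and at 24 h 1 of 40 was higher, where random lists spanned -0.126 to 0.0149. Ribosome biogenesis and MYC targets had 0.02, -0.16 and 0.45, with 22, 3 and 29 of 37 higher. Their random lists spanned -0.127 to 0.0101 at 24 h and -0.113 to 0.297 at 48 h. Plasma cell genes had -0.42 at 48 h, where random lists spanned -0.307 to 0.276. Interferon response genes had -0.18, 0.13 and -0.84, and at 48 h 2 of 29 were higher, where random lists spanned -0.384 to 0.239. Macrophage markers had 2.35, 1.85 and 1.05, neutrophil markers 2.23, 2.55 and 1.12, erythroid markers 1.16, 1.79 and 0.42, and T cell markers -0.69, -0.37 and -0.91. Genes that activation had induced had medians of 0.000896 (823 genes), -0.24 (638 genes) and 0.19 (864 genes), and at 24 h 77.1% of them were lower with the inhibitor. Genes that activation had lowered had medians of 0.51 (956 genes), 0.13 (512 genes) and -0.31 (631 genes). With a 2-fold in place of a 4-fold limit the medians of lost genes were 0.20 at 4 h and 0.041 at 24 h, and that of genes induced at 4 h turned to -0.047. With a mean CPM of at least 1 the lost genes had 0.25 at 24 h. At 24 h random lists matched to the induced genes spanned -0.0736 to -0.0342.

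**Figure D2:**
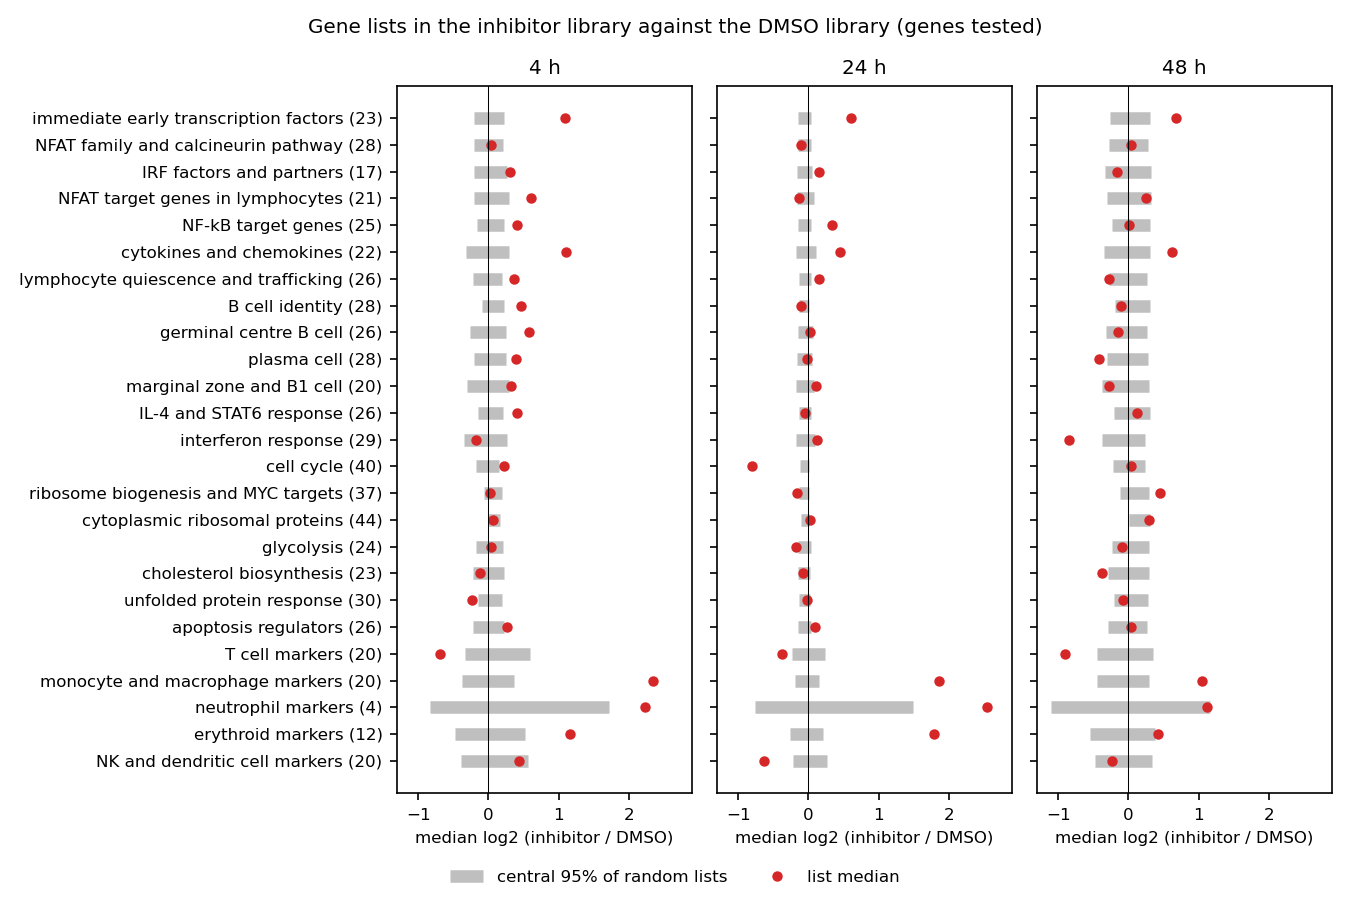
Median log2 ratio of inhibitor to DMSO for each gene list at 4, 24 and 48 h (1 library per arm), with the central 95% of 10000 random lists matched on expression in grey. Macrophage markers lie above the grey range at all 3 times, cell cycle genes below it at 24 h and interferon response genes below it at 48 h.

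The H3K27ac comparisons ask how active regions appear as B and T cells are stimulated, and where the lineages differ. In B cells the lists grew from 3839 regions covering 0.886 Mb at 0 h to 11777, 26187, 63285 and 58578 regions covering 5.16, 19.5, 54.7 and 41.3 Mb at 4, 24, 48 and 72 h. The promoter share went from 47.0% to 58.7%, 44.9%, 20.9% and 24.0%. In T cells 8132, 9442, 36454 and 39840 regions at 0, 4, 24 and 48 h covered 2.42, 3.09, 16.6 and 25.8 Mb. These numbers can move with depth as well as with biology. In B cells they did not simply follow the implied background. It was higher at 0 h (2.25891) than at 4 h (1.10344) and 72 h (0.908193), where more regions were called. At 24 and 48 h, with more regions too, it was higher than at 0 h (2.7433 and 2.34875). Among the 3839 strongest B cell regions of each time, 49.8% at 0 h overlapped one at 4 h, 75.0% at 4 h one at 24 h, 83.7% at 24 h one at 48 h, and 78.1% at 48 h one at 72 h, a mean of 71.6%. T cells showed the same order, with 49.0%, 75.5% and 82.4%, a mean of 69.0%. Counted from the later time of each pair, the shares were 40.6%, 64.1%, 79.1% and 78.4% in B cells. In T cells they were 48.0%, 58.0% and 76.7%, so most values depend on the direction. Of all B cell regions at 4 h, 95.2% lay in regions of 24 h. Of equal numbers of the strongest regions in both lineages, 52.1%, 55.5%, 57.5% and 48.0% of the B cell regions overlapped a T cell region at 0, 4, 24 and 48 h, where random placement gave 0.0995%, 0.302%, 1.24% and 2.34%. Counted from the T cell side the shares were 46.0%, 61.7%, 65.6% and 71.7%, so the lower value at 48 h depends on the direction. The Jaccard index of covered bases was 0.285, 0.339, 0.447 and 0.378.

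Genes of growth were among those that had a called region at 4 h and not at 0 h. In B cells 2.70% of the 37 ribosome biogenesis genes had a region at 0 h and 91.9% at 4 h (exact 95% interval 78.1 to 98.3), against 9.25% and 29.2% of all genes. In T cells the shares were 45.9% and 83.8%, against 23.5% and 27.2% of all genes. Cell cycle genes had a region in 5%, 35% and 95% of cases at 0, 4 and 24 h in B cells, against 9.25%, 29.2% and 49.3% of all genes, and the length of the region lists grew over the same times. B cell identity genes had a region in 92.9% of cases in B cells and 57.1% in T cells at 4 h, and in all 28 cases in both lineages at 48 h. T cell markers showed 19.2% in B cells and 61.5% in T cells at 4 h, and 84.6% and 100% at 48 h. The naive T cell list had 33.3% at 0 h in B cells and 83.3% in T cells, and the T cell activation and effector list had 46.7% and 50.0% at 4 h and 76.7% and 86.7% at 48 h. At 48 h 63.1% of all genes had a region in B cells and 56.0% in T cells. Region counts of single genes differed between times and lineages. With the short list of 0 h in B cells, the lack of a region there does not show that the mark was absent. Irf8 had no region at 0 h and 10, 17, 32 and 27 in B cells later, with the strongest of 48 h over its promoter (chromosome 8, 120733452 to 120748754, fold 56.1). In T cells Irf8 had 0, 6, 22 and 24 regions at 0, 4, 24 and 48 h. Irf4 had 1, 11, 10, 26 and 22 regions in B cells and 0, 4, 14 and 16 in T cells. Egr2 had 0, 3, 6, 24 and 17 in B cells, where its promoter region at 48 h had a fold of 56.7, and 2, 5, 13 and 8 in T cells. Rcan1 had none at 0 and 4 h and 13 at 24 h in B cells, and 1 at 24 h in T cells.

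**Figure D3:**
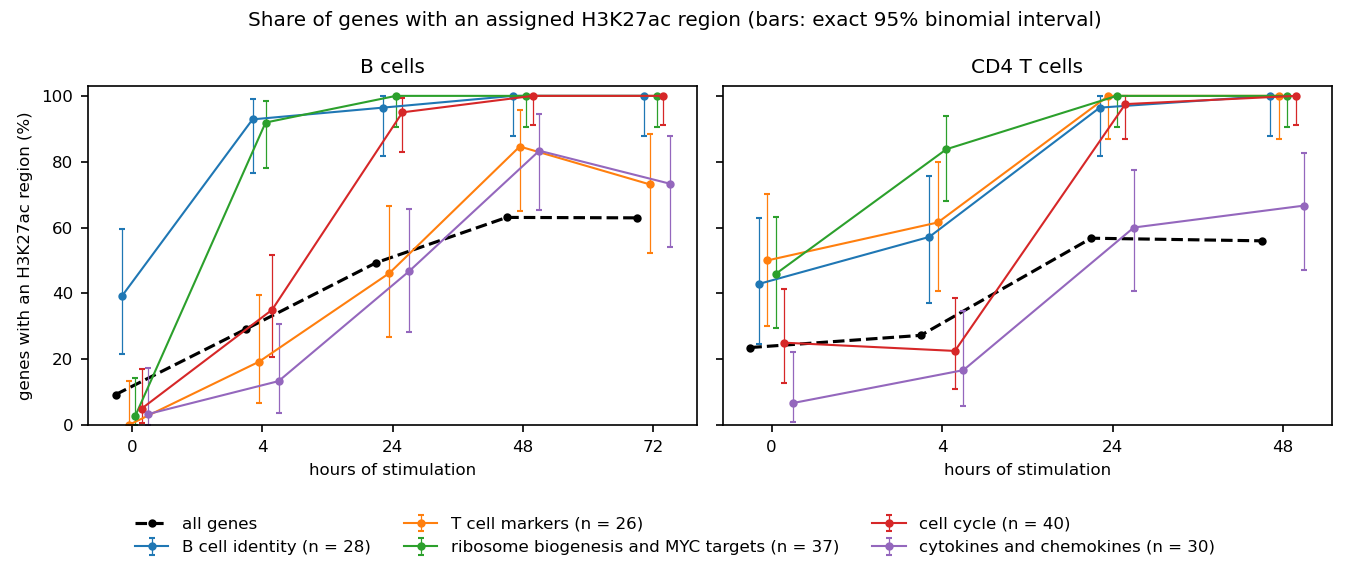
Percent of genes with an H3K27ac region against time (evenly spaced) in B cells and CD4 T cells, for all genes and 5 lists, with exact binomial 95% intervals (1 library per point). Ribosome biogenesis genes reach 91.9% in B cells at 4 h, and T cell markers 100% in T cells at 24 h and 84.6% in B cells at 48 h.

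The HA libraries ask where IRF4, IRF8 and NFATc2 bind together. No HA library from cells without a tagged factor was among the samples. Background shared by the HA precipitations therefore cannot be told from shared binding. The labels of the HA libraries were checked first, since a retroviral coding sequence gives reads at exons and not at introns. The library labelled HA-NFATc2 had 7 narrow regions of high fold over exons of Irf8 and none over Nfatc2 or Irf4. The strongest lay at chromosome 8, 120753276 to 120753779 (fold 83.4) and 120743578 to 120744142 (fold 75.9), and the highest fold in an Irf8 intron was 7.44. No other gene had more than 1 such region in that library. At the first of these places the fold was 19.4 in both the library labelled HA-IRF8 and H3K27ac at 72 h, 5.86 in HA-IRF4 and 3.28 in H3K27ac at 48 h. The library labelled HA-IRF8 and H3K27ac at 72 h each had 1 such narrow region, at this place, with 6.62 and 5.76 the highest folds in an Irf8 intron. Under the fold limit both also had exon regions starting at 120754312 and 120754310 (folds 7.50 and 8.91). Those starting at 120754936 and 120754934 had folds of 7.06 and 8.38. Whether the H3K27ac library of 72 h held Irf8 coding sequence was not tested, and its use as the acetylation reference carries this doubt. No pattern of narrow exon regions was found at Irf4 in HA-IRF4. Of the 10000 strongest summits of the library labelled HA-IRF8, 88.3% lay within 50 bp of an H3K27ac summit at 72 h, at a median distance of 13 bp. The next highest share among the 8 mouse libraries compared, which left out those of 0 and 4 h, apart from the reverse of this pair (87.4%), was 69.1%, for H3K27ac at 24 and 48 h. Over bins of 1000 bp, which are not independent replicates, the rank correlation of fold between these libraries was 0.930, and the next highest of the pairs was 0.846.

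**Figure D4:**
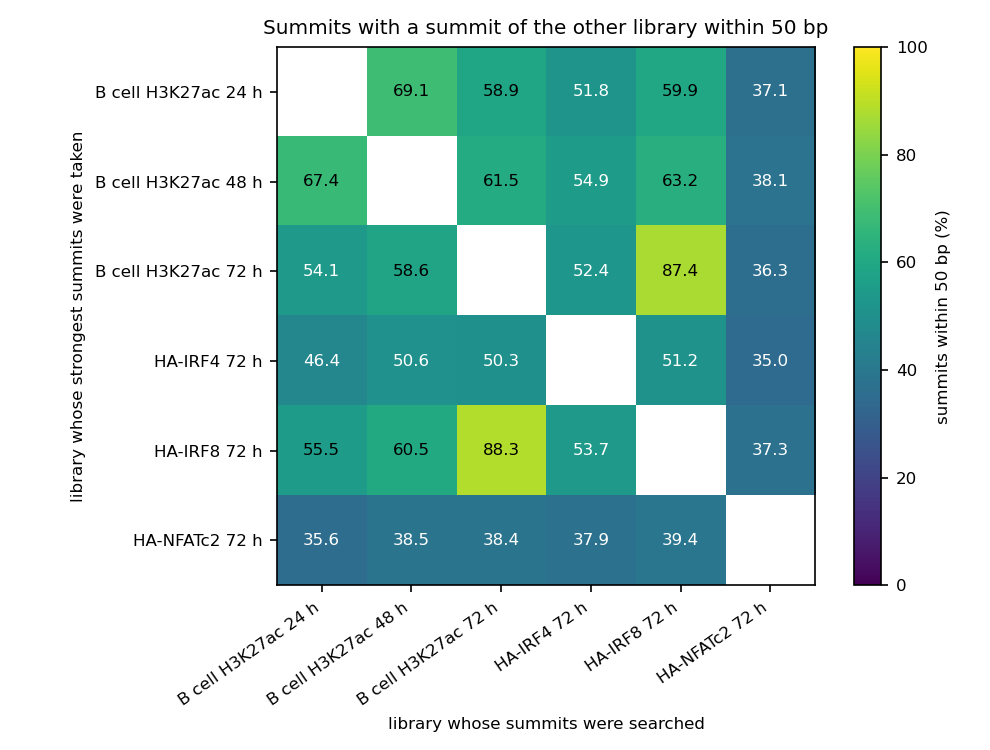
Percent of the 10000 strongest summits of the library in each line of the matrix that lie within 50 bp of a summit of the library in each column, for 6 libraries. The pair labelled HA-IRF8 and H3K27ac 72 h stands apart at 88.3% and 87.4%.

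**Figure D5:**
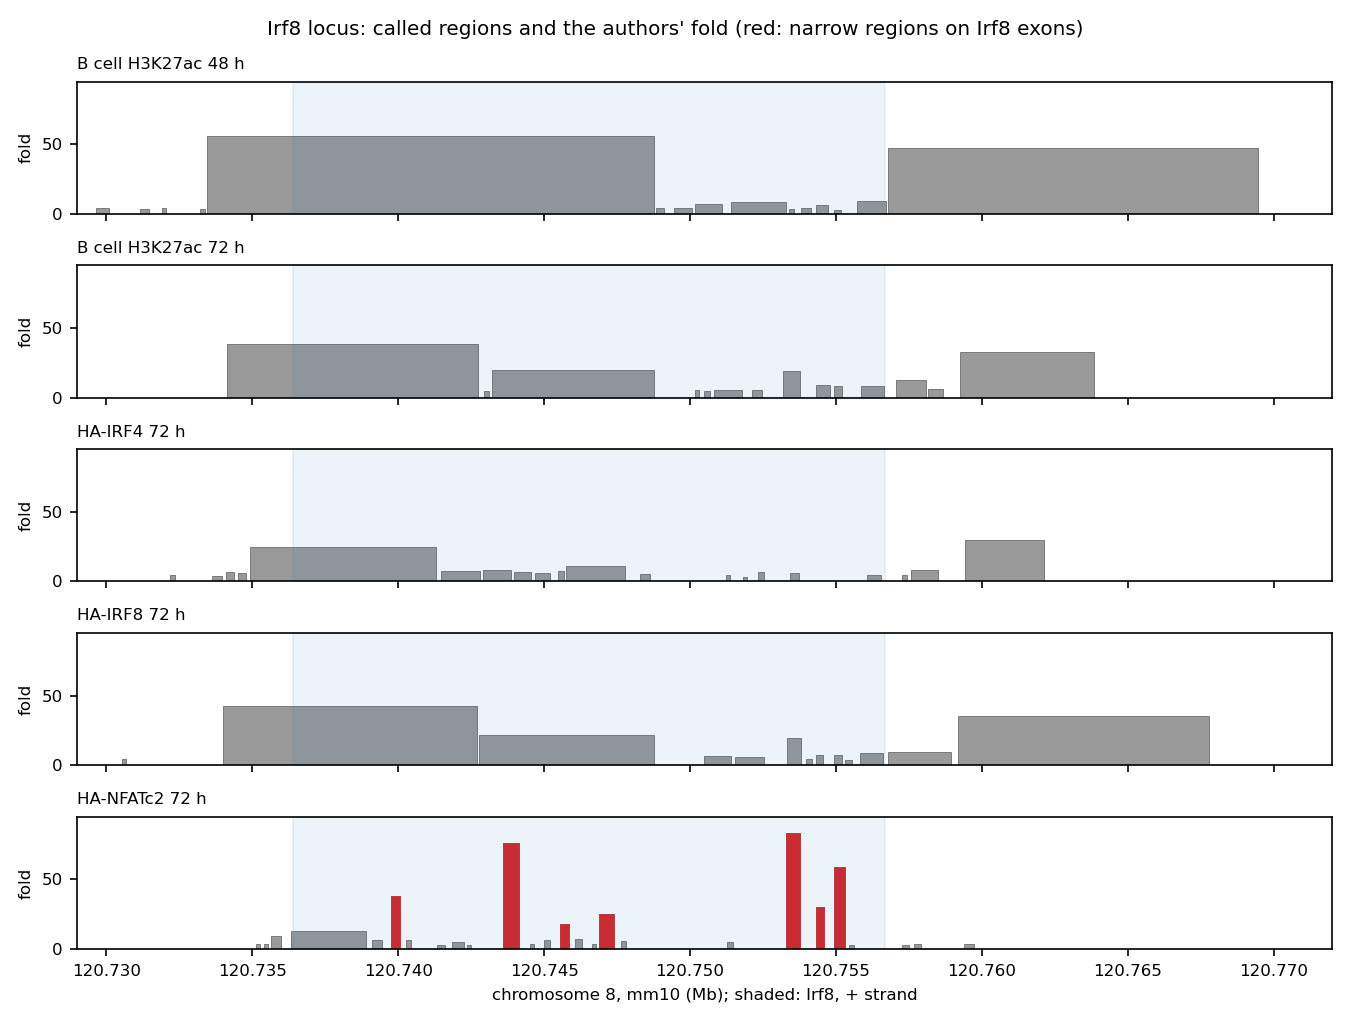
Regions and their fold over background along Irf8 on chromosome 8 (mm10 position in bp) in 5 mouse B cell libraries, with the 7 narrow exon regions of the library labelled HA-NFATc2 in red. The red regions reach a fold of 83.4 and lie over exons.

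With these labels as given, many of the strong regions were common to the 3 libraries. Of the 5000 strongest regions of the library labelled HA-NFATc2, 74.2% overlapped one of HA-IRF4, 76.4% one of the library labelled HA-IRF8 and 68.5% both (Wilson interval 67.2 to 69.8). The share overlapping both others was 58.6% for HA-IRF4 and 57.9% for the library labelled HA-IRF8. With the 1000 strongest regions of each, the 68.5% for the overlap of HA-IRF4, HA-IRF8 and HA-NFATc2 peaks went to 38.3%. The share of HA-IRF4 regions overlapping the library labelled HA-IRF8 was 84.4%. For comparison, H3K27ac at 72 h overlapped that at 48 h in 81.4%. The strongest 5000 H3K27ac regions at 72 h took in 84.0% of HA-IRF4, 92.0% of HA-IRF8-labelled and 75.5% of HA-NFATc2-labelled regions. Merging all regions gave 128996, of which 20505 (15.9%) were in all 3 libraries. Of those, 98.0% lay in H3K27ac at 72 h, 9.18% in H3K27ac at 0 h and 74.9% in T cell H3K27ac at 48 h. These 98.0% say little about sharing, since each shared region is one of the library labelled HA-IRF8, whose summits are close to those of H3K27ac. The acetylated share at 72 h was high where that library was included, 79.3% of 12129 regions with HA-IRF4, 68.2% of 1869 with the library labelled HA-NFATc2 and 47.9% of 24319 alone. Without it the share was 13.2% of 1152 regions of HA-IRF4 and the library labelled HA-NFATc2, 3.90% of 39712 of HA-IRF4 alone and 1.20% of 29310 of the library labelled HA-NFATc2 alone. The 10 shared regions with the highest folds lay in all 9 H3K27ac libraries, resting ones included, and are not described. They were kept in the overlap shares, since only mitochondrial summits were left out. Outside 0 h H3K27ac, a choice made after the data were seen, the first were an intron of Camk2b (chromosome 11, 6006263 to 6006878), a kinase gene, a region upstream of Tldc1 (chromosome 8, 119782658 to 119788493), Pfkp (chromosome 13, 6629098 to 6639127), which encodes a glycolytic enzyme, and the promoter of Tfeb (chromosome 17, 47736803 to 47740703), a factor of lysosome genes, whose lowest folds among the 3 libraries were 43.9, 29.0, 27.5 and 25.3. HA-IRF4 had its strongest region at Egr2 over the promoter (fold 48.2) and at Irf4 over its own promoter (chromosome 13, 30748656 to 30754110, fold 28.0).

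Genes near these regions were asked whether they move with activation or the inhibitor. No set passed with camera in the edgeR design after adjustment (smallest adjusted p 0.183). The 1997 tested genes at the 2000 strongest shared regions had an unadjusted p of 0.0267 in the upward direction at 4 h. Their median of 0.26 lay below that of matched random lists (0.309 to 0.435), so median and test differ. At 24 and 48 h and for the inhibitor the unadjusted p was 0.544, 0.960 and 0.871. The inhibitor contrast averages over times. At single times, with 1 library per arm, the median log2 ratio of inhibitor to DMSO was 0.0499 at 4 h (random lists -0.0173 to 0.0298). It was -0.0237 at 48 h (random lists 0.02 to 0.0848). Outside 0 h H3K27ac the median at 4 h was -0.0452 (random lists -0.0385 to 0.00999), so its sign depends on the regions. With regions outside 0 h H3K27ac, a choice made after the data were seen, the direction was up at both 24 and 48 h (unadjusted p 0.0290 and 0.0355, or 0.0258 and 0.0487 with an estimated correlation), where at 48 h it had been down, and at 4 h the p was 0.213. Nor did genes with regions of 1 library alone pass. In the downward direction the unadjusted p at 24 and 48 h was 0.0233 and 0.0384 for the 1285 of the library labelled HA-IRF8, 0.0334 and 0.0459 for the 871 of the library labelled HA-NFATc2, and 0.0689 and 0.157 for the 1217 of HA-IRF4. With an estimated correlation it was 0.155, 0.337 and 0.283 at 24 h. In the same order of libraries, the medians of inhibitor over DMSO at 4 h were 0.104, 0.118 and 0.101, each above its random lists. At 48 h they were -0.000141, -0.152 and -0.00253. Only that of the library labelled HA-NFATc2 lay outside its random lists (-0.0282 to 0.0679).

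In human CD4 T cells the question was whether NFAT and IRF4 share sites, with the factors mapped at different times. NFATc1 sites were nearly a part of NFATc2 sites, and NFAT sites lay mostly within the larger IRF4 list. Of 7054 NFATc1 regions 88.6% overlapped one of NFATc2 and 71.7% one of IRF4, and of 15282 NFATc2 regions 62.2% overlapped one of IRF4, where random placement gave 0.453%, 1.61% and 1.77%. Among the 5000 strongest regions of each, 77.2% of NFATc1 overlapped NFATc2 but 28.6% overlapped IRF4, and 24.9% both (Wilson interval 23.7 to 26.1). Merging gave 62106 regions, of which 4459 (7.18%) were in all 3 libraries and 46823 (75.4%) in IRF4 alone. Ranked by the lowest of the 3 folds, most of the first 10 shared regions were intergenic with like folds in the 3 libraries (the first at ANKRD20A12P, lowest fold 116), and they are not described. No such regions were removed from the shares above. At 63 of the shared regions the assigned gene was on the T cell activation and effector list. Of these 63, the first in the same ranking was upstream of TBX21, the T helper 1 factor (hg19 chromosome 17, 45796695 to 45799359), with folds of 24.2, 17.3 and 28.7 for IRF4, NFATc1 and NFATc2. A region upstream of IL2 (chromosome 4, 123379079 to 123380869) had folds of 13.8, 17.3 and 25.1, and one in an intron of NFATC1 (chromosome 18, 77282403 to 77285077) 11.7, 21.2 and 28.7. RCAN1 showed the NFAT side, with its strongest fold at 6.90 for IRF4 and at 25.0 and 24.6 for NFATc1 and NFATc2. The activation marker gene CD69 had its strongest IRF4 region over the promoter (fold 16.6). Its strongest NFATc1 and NFATc2 regions (folds 30.6 and 36.9) lay at another place, upstream. PRDM1 had its strongest IRF4 region over the promoter (fold 22.1), where NFATc2 had 11.4. PAX5 and BCL6 had no region for NFATc1.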

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

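Every test of an explanation in this part, the splits included, was set down after the result it tests was seen, and some of its bounds were later restated to match the code, with no verdict changed. The comparison that pools DMSO and untreated libraries was also chosen after the data were seen.

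Whether the effect of 11R-VIVIT differs between 4, 24 and 48 h cannot be told with 1 inhibitor library per time. With the DMSO and untreated libraries of a time as joint controls edgeR called a difference in 7871 of 11229 genes, 2485 of them higher at one time and lower at another. Each time on its own gave 3032 genes higher and 3048 lower at 4 h, 1303 and 1578 at 24 h, and 3525 and 3646 at 48 h. The only spread in this fit is that between a DMSO and an untreated library of the same time, with 3 residual degrees of freedom, so it takes no account of how inhibitor cultures vary and large counts were to be expected. Genes chosen after their values were seen include Xcl1 (log2 changes of 0.49, -0.72 and 4.53 at 4, 24 and 48 h), Egr1 (2.1, -0.20 and 1.36) and Irf4 (0.79, 0.50 and -0.18).

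No list difference between times held with an estimated correlation (smallest adjusted p 0.211). With the preset correlation, the cell cycle list was lower at 24 h than at 4 h relative to controls (camera adjusted p 7.15e-18) and higher at 48 h than at 24 h (1.32e-12), and the interferon list was lower at 48 h than at 24 h (1.35e-06). Other lists were called with the preset correlation too. Among them were B cell identity (lower at 24 h than at 4 h) and ribosome biogenesis and MYC targets (higher at 48 h than at 24 h). The median chi-square per gene between single libraries, where sampling alone gives 0.455, was 1.70, 6.09 and 2.44 for DMSO and untreated at 4, 24 and 48 h, and 45.0, 9.96 and 51.6 for inhibitor and DMSO.

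Markers of macrophages, neutrophils and erythroid cells were higher with the inhibitor at 4 h, with Lyz2 at 50.9 against 9.65 CPM (chosen after its values were seen). The DMSO library was itself low in macrophage markers, with a median of -0.28 for DMSO over untreated beside 2.35 for inhibitor over DMSO. For neutrophil and erythroid markers the medians for DMSO over untreated were 0.05 and -0.02. A lower share of B cell RNA alone would raise every other cell type alike. The rise was not alike, since T cell markers had a median log2 ratio of -0.69, with Cd3e at 0.444 against 2.23 CPM. NK and dendritic cell markers had a median of 0.43 with 13 of 20 higher, within their random lists (-0.393 to 0.57). The T cell list also holds Il7r, which rose with activation, and the inhibitor could act on T cells too. The T cell markers therefore cannot decide whether the share of B cell RNA was lower. More RNA of macrophages, neutrophils and erythroid cells stays open, since the erythroid markers, globin and haem genes for the most part, had a median of 1.16 with 12 of 12 higher, although the globin pairs among them share reads. Against the 0 h library, the 4 h inhibitor library was lower in Lyz2 (50.9 against 149 CPM) and Csf1r (40.7 against 194 CPM). It was higher in S100a8 (5.65 against 2.72 CPM) and Hba-a1 (49.2 against 25.8 CPM), all chosen after their values were seen. The inhibitor may have kept macrophages, neutrophils and erythroid cells alive, though that alone would hardly lift a marker above its 0 h level. Or the cultures may have differed in their cells at the start. The labels name a kit for isolating resting B cells, which should remove such cells, and with 1 culture per arm no test here separates these.

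The HA libraries raise the question of what the labels stand for. In the library labelled HA-NFATc2, 7 narrow regions of high fold lay over exons of Irf8, which is what an Irf8 coding sequence in that library would give, and ordinary chromatin signal at Irf8 is argued against by the introns, whose highest fold was 7.44 beside 83.4 over an exon. Active regions coinciding in any pair of libraries are argued against as the source of the 88.3% of summits that the library labelled HA-IRF8 shares with H3K27ac at 72 h, since the next pair of the 8 libraries compared reached 69.1%. A candidate explanation is that the library labelled HA-NFATc2 came from cells with HA-IRF8, and that the library labelled HA-IRF8 held an H3K27ac precipitation or one much like it. The library labelled HA-IRF8 and H3K27ac at 72 h had 1 such narrow Irf8 exon region each (fold 19.4 in both, introns 6.62 and 5.76) and HA-IRF4 none at Irf4, so exon regions alone do not tell which factor a library held, whether labels were exchanged stays open, and no biological explanation was tested.

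Immediate early genes were higher with the inhibitor, with Egr1 at 5186 against 1251 CPM, Nr4a1 at 8088 against 2780 and Fos at 147 against 32.5 at 4 h (chosen after their values were seen). RNA of macrophages is argued against as the whole cause, since the macrophage list gained 316 CPM in sum at 4 h and the immediate early list 13375. The scaling of the 4 h inhibitor library is argued against too, since the list median was 0.94 with total counts alone, 1.1 with TMM and 1.17 with RLE factors, where the median of all genes was -0.19, -0.03 and 0.04. The inhibitor itself, handling of the culture and stress at harvest stay open, and with 1 culture per arm could not be compared.

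The splits of the 6 DMSO and inhibitor libraries into groups of 3 are 10 in number, too few for a share under 0.05. The real split called 61 genes and the highest other split 1, so 1 of 10 splits was as large. For DMSO and untreated libraries the real split called 0, the highest other 0, and 10 of 10 splits were as large.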

How the results depend on the processing

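Chosen after the data were seen were the leaving out of single libraries, leaving out the 0 h H3K27ac libraries, and the regions outside 0 h H3K27ac. The 3 alternatives set for motif shares were not run, since no genome sequence was used. The replicate numbers pair no libraries, since each group holds 1, and DMSO and inhibitor libraries of a time were matched by the time term. For each value that moved, the cause was not tested unless the setting itself gives it, as a stricter threshold does.

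The direction of the main counts was kept with RLE size factors, and no count moved by more than 1.5 times. The share of inhibitor calls that were higher was 91.8% with TMM and 98.4% with RLE. The inhibitor against DMSO was the least stable comparison, with 61 genes. It gave 113 without a count filter, 22 at a mean CPM of at least 5, 3 at adjusted p 0.01, 635 with DESeq2 (493 higher and 142 lower), 0 with limma on log2(RPKM + 1), 1 without the 4 h libraries and 0 without the 24 h libraries. The 6 libraries of the pair alone gave 10 with the time term, and 0 without it. Leaving out 1 library gave 0 (without the DMSO 4 h library, among others) to 644 (without the inhibitor 48 h library).

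The counts for activation 4 h against 0 h, activation 24 h against 0 h and activation 48 h against 0 h (6108, 5056 and 6264) moved too. At adjusted p 0.01 they were 2852 at 24 h and 4150 at 48 h. Without the inhibitor libraries they were 9503, 9190 and 9461 at 4, 24 and 48 h, and without the DMSO libraries 3008 at 24 h. Leaving out 1 library gave 2649 (without the untreated 24 h library) to 6972 (without the inhibitor 48 h library) at 24 h. The other activation counts stayed within 1.5 times. Of 63 list calls 0 held with an estimated correlation. Among values for single named genes, 41 no longer passed at adjusted p 0.01, 28 with limma, 6 with RLE size factors, 2 with DESeq2, 14 at a mean CPM of at least 5, 11 without the DMSO libraries, and 13 to 36 when 1 library other than inhibitor 48 h was left out. Of the fewer values that the smaller sets of libraries give, 20 no longer passed with 6 libraries and no time term, 16 with the 6 libraries of the pair, 20 without the 24 h libraries, 20 without the 4 h and 13 without the 48 h libraries. None reversed under any setting.

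With a 2-fold in place of a 4-fold limit, the median for genes induced at 4 h turned to -0.047 from 0.000896, that for genes lost at 4 h went to 0.20 from 0.51, for induced at 24 h to -0.15 from -0.24 and for lost at 24 h to 0.041 from 0.13. With a mean CPM of at least 1 the medians of lost genes were 0.62, 0.25 and -0.21 at 4, 24 and 48 h.

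Genes near shared HA regions had an unadjusted camera p of 0.0988 at 4 h with the 500 strongest regions and 0.213 outside 0 h H3K27ac, against 0.0267. With promoter regions it was 0.00916, or 0.0694 with an estimated correlation. Outside 0 h H3K27ac the p was 0.0290 at 24 h and, with the direction turned to up, 0.0355 at 48 h.

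At −log10 q of at least 10 the mean overlap over time was 56.8% in B cells (71.6%) and 50.5% in T cells (69.0%), the share of B cell regions in T cells at 48 h 70.4% (48.0%), the 3-way human overlap 18.6% (24.9%) and the acetylated share of shared HA regions 99.8% (98.0%). Requiring an overlap of 0.5 of the shorter peak gave 66.9% for T cells over time and 46.8% for B against T cells, and 0.5 of the factor peak gave 84.1% for shared HA regions. Without the 0 h library the overlaps over time were 89.2% in B and 79.7% in T cells. Counted from the later time, the B cell shares were 61.1% for 24 h in 4 h, 79.8% for 48 h in 24 h and 89.6% for 72 h in 48 h. The 3-way HA overlap of 68.5% went to 38.3% with the 1000 strongest, 63.3% away from promoters and 58.8% without regions in a 0 h H3K27ac library. The human one went to 17.1% with the 1000 strongest and 28.4% away from promoters. Ranking by pileup gave the same order of peaks as fold within a library and tests nothing.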

Other observations

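Few list members covered the response to the aryl hydrocarbon receptor. Ahr mRNA rose from 21.1 to 855 CPM at 4 h (5.20 ± 0.37, edgeR adjusted p 0.000124) and was at 86.7 CPM in the untreated library at 48 h. Its target Cyp1a1 had no counts at 0 h and in the untreated library at 4 h, 32.4 CPM at 24 h and 4.59 at 48 h, where the inhibitor library had 72.3 CPM. Cyp1b1 had 2.51 CPM with DMSO and 21.7 CPM with the inhibitor at 48 h. Ahrr, the repressor of the receptor, chosen after its values were seen, had 1.14 CPM at 0 h, 0.0787 at 4 h, 10.2 at 24 h and 2.33 at 48 h in the untreated libraries.

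Single genes of the unfolded protein response list rose far at 4, 24 and 48 h. Chac1, which degrades glutathione, changed by 7.63 ± 1.00, 7.02 and 6.90 at 4, 24 and 48 h, Trib3 by 4.79 ± 0.92 at 4 h, and Asns, the enzyme that makes asparagine, by 6.14 ± 0.41 at 48 h. All 3 are targets of the factor ATF4. The cytokine and chemokine list had no camera call (adjusted p 0.205, 0.570 and 0.684), but the chemokine gene Ccl22 climbed at each time, from 5.46 CPM at 0 h to 97.6, 936 and 2386 CPM in the untreated libraries at 4, 24 and 48 h, and was at 4670 CPM with the inhibitor at 48 h.

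T cell genes carried H3K27ac in B cells. At 48 h 84.6% of 26 T cell markers had a region in B cells, while 63.1% of all genes did, and at 72 h the shares were 73.1% and 62.9%. Markers of other lineages stayed below the share of all genes at 48 h, with neutrophil markers at 12.5% and erythroid markers at 35.3%. In mRNA 8 of 20 T cell markers fell at 48 h and 2 rose, with no camera call (adjusted p 0.193). Cd4 and Cd8a changed by -6.75 and -5.04, while Thy1, chosen after its values were seen, was at 67.5 CPM in the untreated library against 5.99 at 0 h.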
